A study of Mus musculus with 9 samples.

How the data were processed

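The series holds 9 samples from tumour-infiltrating CD8 T cells (TIL) of mice that carried MethA, a chemically induced mouse sarcoma line. Per the labels, the cells recognised a mutated peptide of PDPR, a neoepitope of this tumour, and were sorted into low, medium and high avidity cells from untreated mice. How avidity was read in the sort, and how many mice were pooled, is not given in the sources used here. Each of the 3 avidity classes gave 1 droplet library of 5' gene expression, 1 library of antibody-derived tags and 1 library of T cell receptor (TCR) contigs. There are therefore no replicates, and no test between classes was made. Cells were not treated as replicates.

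The deposited matrices give unique molecular identifier (UMI) counts, as whole numbers, for every barcode that had any count, not only for cells. Per the submitters' processing notes, Cell Ranger was used with genome mm10, and per the file headers the matrices come from Cell Ranger 4. The version used for the contigs is not stated. The tag libraries have no tables of their own, since their counts for 4 antibodies (PD-1, LY108, TIM3, CX3CR1) stand in the gene expression matrices. The feature list holds 0 hashtags and no isotype control. The deposited contig tables list each assembled TCR contig with its V and J genes, CDR3 and UMI counts. All 12 tables were used, and 0 of their columns were left without a meaning. For the high avidity gene expression library, the label's description says medium avidity, while its title and cell type say high avidity. The title and cell type were followed. Raw reads were not analysed here.

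Gene identifiers were joined to GENCODE M21, which is on GRCm38, the assembly also called mm10. Of the 32285 gene identifiers, 32235 were found there. Coordinates are on that build, and the length of introns per gene was taken from it as gene span minus merged exons.

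The rule for calling cells, the gene lists, the clonotype definition, the named genes and most alternatives were fixed before the data were examined. The cell rule kept barcodes with at least 1/10 of the UMIs of the 99th percentile of the largest barcodes. It set minimums of 11888, 11918 and 11373 UMIs in the low, medium and high library and kept 489, 424 and 853 cells after the other filters. Of the barcodes that the contig tables mark as cells, those minimums kept 8.43%, 12.8% and 25.3%. An alternative fixed with it, a minimum of 1000 UMIs, kept 99.7%, 99.8% and 99.9% of them and was taken as the main setting. This switch was made after the data were seen, and values under the first rule that differ in direction are given for several results.

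Barcodes also needed at least 300 genes and at most 10% mitochondrial UMIs, which left 3296, 3245 and 3807. Scrublet called 0 doublets in each library and so removed none. Barcodes with more than 1 productive TRB CDR3 were removed as doublets: 60 in the low, 102 in the medium and 230 in the high library. The 3 libraries were pooled, log-normalised and clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes without TCR and immunoglobulin genes, 30 principal components, 15 neighbours and resolution 1, with no integration. The plan named clusters by the most cell type markers among their leading genes, and the numeric conditions were set after the data were seen. A cluster was named CD8 T-like when most of its cells had CD8 and CD3 UMIs, fewer than 3 markers of another cell type were among its 20 leading genes, and over 50% of its barcodes carried a TCR contig. The last condition kept out an intron-rich cluster with 0% of the called cells in the low library, 15.3% in the medium and 15.1% in the high. The marker condition kept out a cluster with macrophage genes, of which 64.4% of barcodes carried a TCR contig (66, 68 and 91 cells). A further cluster was left out, in which 25.6% of barcodes carried a TCR contig and the median depth was 0.272 of that of its libraries (74, 7 and 1 cells).

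UMIs were summed over the CD8 T-like cells of each library and scaled to CPM, a gene's share of the UMIs of all genes except TCR genes. Per gene, the log2 ratio of CPM between libraries has an exact conditional binomial 95% interval for a pair of Poisson counts. Shares have exact Clopper-Pearson 95% intervals. These intervals cover counting error only, and those of medians over genes or clonotypes reflect the spread among them. None says anything on differences between animals or preparations. For each of 12 gene lists, the median log2 ratio of the measured members (at least 50 UMIs in the libraries compared) has an order-statistic 95% interval, and its percentile was read among 10000 random lists matched on expression. A gene with 0 UMIs on one side is given as a bound against a floor of 3 UMIs in that library. Shares of cells with a UMI were computed after thinning each cell to 2500 UMIs. Free RNA was read from barcodes with 100 to 300 UMIs, as was the background of the tags.

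Genes were named by this rule. Among genes with at least 50 CPM in 1 library compared and outside the TCR, immunoglobulin, mitochondrial, ribosomal, unnamed and sex-linked control genes, the 12 largest ratios each way were taken for high over low, and the 5 largest each way for the other comparisons. From each list came the measured members with the largest ratios each way, and Tcf7, Pdcd1, Tox, Havcr2, Gzmb, Ifng, Mki67, Cd8a, Cd5 and Nr4a1 were always taken. Genes named outside it are said to be chosen after their values were seen.

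A clonotype is a pair of productive TRA and TRB CDR3 nucleotide sequences with their V genes in a CD8 T-like cell with 1 TRB. Where a cell had more than 1 TRA, the one with most UMIs was used. Diversity was compared after thinning each library to 1275 cells over 100 draws. Expanded clonotypes have at least 5 cells.

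The depth of the gene expression libraries was 48911106 UMIs (low), 43566486 (medium) and 52792805 (high) over all barcodes. On simulated counts of the same depth without a difference, the high over low interval covered the truth for 93.2% of 10338 genes. With a simulated 1.5-fold difference, it excluded 0 for 97.9% of 47 genes and covered the truth for 87.2%, below the nominal 95%. With a 2-fold difference it covered the truth for 89.8% of 49 genes, and with a 4-fold difference it excluded 0 for 100% of 47 genes and covered the truth for 93.6%.

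Alternatives covered the cell rule, the mitochondrial limit (5%), doublets, clustering resolution (0.5 and 2), the cell gate, scaling, the low-count filter, clone size, the list summary, tag scaling and background, clonotype definition, contig UMIs (at least 3), barcodes found in more than 1 library, clone size limits (3 and 10 cells) and thinning. The planned split by hashtag was not run, because the feature list holds none. Alternatives on intron length, on free RNA, on the intron-rich cluster and on medium in place of low were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.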

Results

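Gene expression, 4 surface proteins and paired TCR chains were measured in the same droplets for TIL of low, medium and high avidity for the mutated PDPR peptide, with 1 gene expression library per class. The comparisons ask how the transcriptional state, surface phenotype and clonal make-up of T cells against 1 tumour antigen differ with avidity. After filtering, 3236 cells were called in the low, 3143 in the medium and 3577 in the high library. CD8 T-like cells made up 80.4% (95% interval 79.0 to 81.7) of the low, 72.7% (71.1 to 74.2) of the medium and 73.5% (72.0 to 74.97) of the high library. An intron-rich cluster present only in the medium and high libraries was kept out, and with it the shares there were 88.0% and 88.6%. The CD8 T-like cells held 15430102, 16735944 and 25321496 UMIs, with medians of 4785, 6214.5 and 7786.5 UMIs per cell. Xist, the X-inactivation RNA of females, had 3397, 4002 and 5863 UMIs and the Y-linked Ddx3y 0, 0 and 1, which fits females in all 3 libraries.

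Several kinds of CD8 T-like cells were seen in all 3 libraries. A cluster led by Hist1h2ae and Stmn1, a histone and a microtubule gene of dividing cells, held 6.77% of CD8 T-like cells in the low library (5.83 to 7.80), 5.91% in the medium (4.98 to 6.96) and 9.51% in the high (8.41 to 10.7). A cluster led by Dapl1, Ccr7 (lymph node homing receptor) and Tcf7 (transcription factor of memory and stem-like T cells) held 2.11%, 4.25% and 6.77%. A cluster with Xcl1, Csf2, Il2 and Gzma (cytokine genes and a granzyme) held 3.15%, 6.74% and 8.37%. A heat shock cluster led by Hspa1a and Fos held 5.77%, 7.92% and 3.23%, and an interferon-response cluster led by Ifit3 held 2.73%, 2.01% and 1.71%. The largest cluster held 2048 cells of the low library against 41 of the medium and 46 of the high. Clusters led by granzymes Gzmd to Gzmg and by Spp1 and Penk held 10 and 4 cells of the low, 324 and 151 of the medium and 481 and 284 of the high library. The libraries were clustered without integration. The largest cluster took 78.7% of CD8 T-like cells of the low library, against 1.80% of the medium and 1.75% of the high. Shares of all other clusters depend on this split, so no difference between libraries is read from any cluster size.

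Low and high avidity TIL were compared first, across 12 gene lists. Proliferation genes were higher in the high avidity library: the list's median log2 ratio was 0.63 (0.38 to 0.70), 19 of 20 members had an interval above 0, and the median exceeded 99.98% of random lists. Mcm6 and Mcm5, parts of the replicative helicase, had log2 ratios of 0.92 (0.81 to 1.04) and 0.89 (0.73 to 1.05), and Mki67, a marker of dividing cells, 0.66 (0.57 to 0.75). In a cluster led by myeloid genes, thinned shares of cells with an Mki67 UMI also stood at 4.21% in low and 16.9% in high. That cluster held only 115 low and 77 high avidity cells, so these shares are imprecise. Type I interferon response genes were lower: their median was -0.26 (-0.66 to 0.052), below all 10000 random lists, with 9 of 14 intervals below 0 and 1 above. The antiviral genes Rsad2 and Ifit3 had -0.81 (-1.24 to -0.38) and -0.71 (-1.04 to -0.39), on 96 and 164 UMIs in the low library. Ifit3 lay mainly in the interferon-response cluster, which held 71 low and 45 high avidity cells. It stood there at 411 and 322 CPM in low and high, against 2.65 and 2.37 CPM in other CD8 T-like cells. Under the first cell rule, which kept 489 and 853 cells of these libraries, the interferon median was 0.0080 and the proliferation median -0.060. Over all called cells the proliferation median was -0.032, so its direction holds for CD8 T-like cells with the 1000 UMI minimum.

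Genes of inhibitory receptors and exhaustion were higher in the high avidity library in CPM but not relative to the median gene. All 18 members had a ratio above 0, 12 with an interval above 0, and the median was 0.32 (0.17 to 0.46). Pdcd1, which encodes the inhibitory receptor PD-1, went from 564 CPM in the low to 701 in the medium and 810 in the high library (log2 high over low 0.52, 0.49 to 0.56). Entpd1 (CD39) had a ratio of 0.84 (0.75 to 0.93) and Tox, a transcription factor of exhausted T cells, 0.52 (0.46 to 0.59). Havcr2 (TIM3) had 0.36 (0.31 to 0.42). Cd160 and Cd101 had 0.079 and 0.067, with intervals that span 0. The median ratio over all measured genes was 0.34, and scaling by median-of-ratios size factors instead of CPM moved the list's median to -0.018. The median exceeded 90.8% of random lists matched on expression and 71.3% of those also matched on intron length. Under the first cell rule it was 0.52, and over all called cells, which bring in other cell types and the intron-rich barcodes, 1.11.

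**Figure D1:**
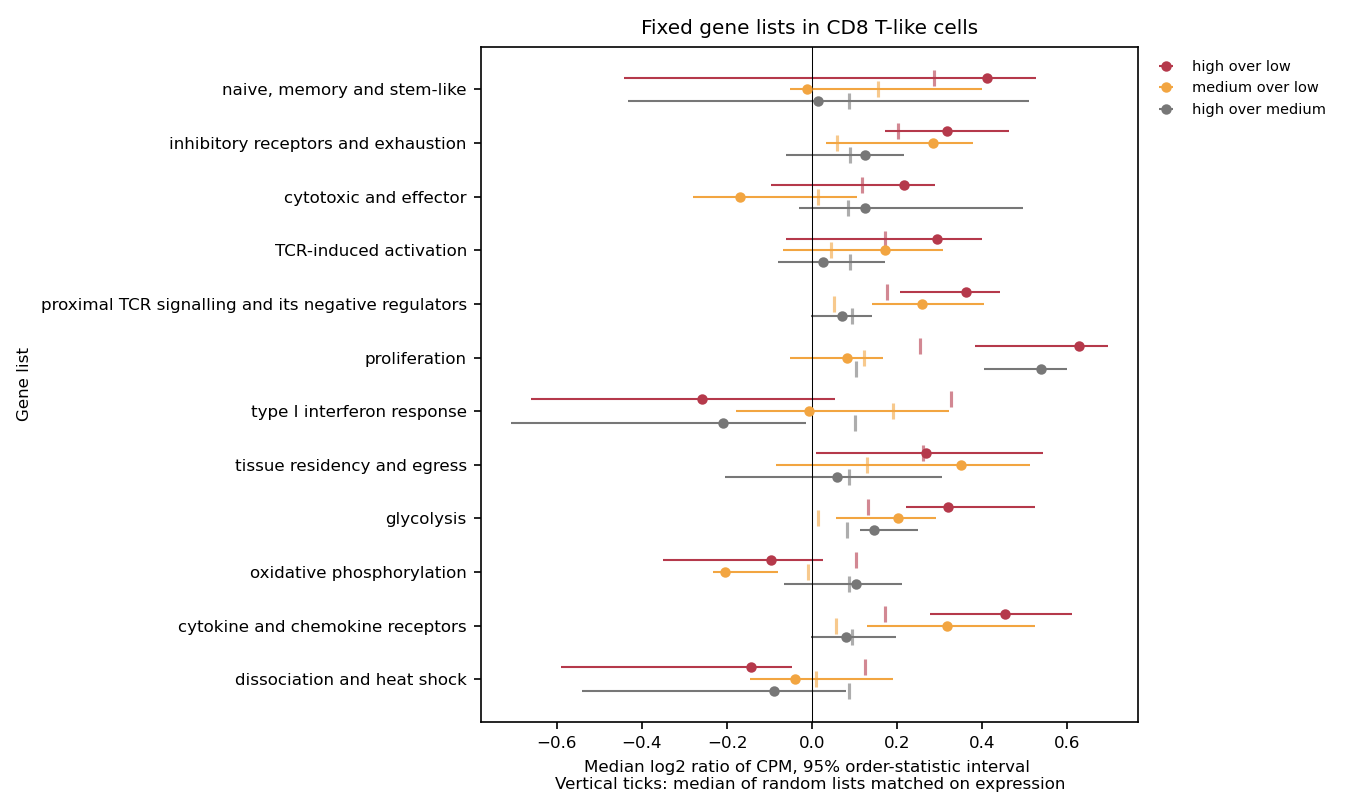
Points show the median log2 ratio of CPM (horizontal axis, no unit) of the measured members of 12 gene lists in CD8 T-like cells, with 95% order-statistic intervals, and vertical ticks the median of random lists matched on expression. Proliferation stands highest for high over low (0.63) and high over medium (0.54), and the type I interferon response lowest for both (-0.26 and -0.21).

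In CPM, cytokine receptor genes were higher in the high avidity library, and proximal TCR signalling genes lay close to the median gene but above most random lists matched on expression. Cytokine and chemokine receptors had a median of 0.45 (0.28 to 0.61) with 14 of 15 intervals above 0, among them Il12rb2 (0.999, receptor for IL-12) and Il2rb (0.65, receptor for IL-2 and IL-15), while Il2rg had 0.071. Proximal TCR signalling genes and their negative regulators had a median of 0.36 (0.21 to 0.44) with 21 of 26 above 0 and 3 below, against 0.34 over all measured genes. The receptor median exceeded 99.88% and the proximal median 99.56% of random lists. Under median-of-ratios scaling the receptor and proximal medians were 0.12 and 0.027, and relative to genes of like intron length 0.11 and 0.050. Cblb, a ubiquitin ligase that restrains TCR signalling, had 1.18 (1.13 to 1.23) and Cd247, the TCR zeta chain, 0.87 (0.80 to 0.95). Cd8a had 0.22 (0.19 to 0.25), Cd3d had -0.092 and Cd8b1 -0.091. TCR-induced genes went both ways: the median was 0.29 (-0.060 to 0.40), with 13 of 19 intervals above 0, as for Il2ra (0.70), Irf4 (0.68), Cd5 (0.50) and Nr4a1 (0.40), and 4 below, as for Dusp2 (-0.35) and Cd69 (-0.34). With genes of under 5 kb of introns only, that median was -0.073, and under median-of-ratios scaling -0.042.

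Cytotoxic and effector genes had a median of 0.22 (-0.10 to 0.29), with 15 of 22 intervals above 0 and 5 below, and of -0.12 under median-of-ratios scaling. Zeb2 and Tbx21, transcription factors of effector cells, had 0.87 and 0.70, Gzmb (granzyme B) 0.22 and Ifng (interferon gamma) 0.21, against -0.40 for Tnf and -0.29 for Ccl4. The naive, memory and stem-like list had a median of 0.41 (-0.44 to 0.53), with 8 of 13 intervals above 0 and 3 below. That median was -0.34 with genes of under 5 kb of introns only and -0.061 relative to genes of like intron length. Bach2, a repressor of effector genes with long introns, had 2.12 (1.91 to 2.33), Myb 0.88 (0.68 to 1.09) and Tcf7 0.40 (0.083 to 0.73), while Il7r, the IL-7 receptor, had -0.50 (-0.59 to -0.41). Tissue residency genes had a median of 0.27 (0.0082 to 0.54), with 9 of 13 intervals above 0 and none below. That median was -0.067 under median-of-ratios scaling and 0.019 with each clonotype weighted equally. Itgae (CD103) had 2.06 (1.40 to 2.80), from 21 UMIs in the low and 144 in the high library, and Itgb7 had 0.76. Itgae lay mainly in the cluster with Xcl1, Csf2 and Il2, at 35.4 and 97.4 CPM in low and high, against 0.598 and 0.9998 CPM in other CD8 T-like cells.

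Glycolysis genes had a median of 0.32 (0.22 to 0.52) in CPM, above 98.3% of random lists (96.3% with intron length also matched), of -0.016 under median-of-ratios scaling and of 0.17 under the first cell rule. In CPM 14 of 15 intervals were above 0, as for Eno1 (0.68) and the glucose transporter Slc2a1 (0.64), against 0.044 for Gapdh and -0.10 for Hk2. Oxidative phosphorylation genes had a median of -0.10 (-0.35 to 0.026), with 9 of 16 intervals below 0, as for Ndufa1 (-0.70) and Uqcrb (-0.43), and 3 above, as for Atp5b (0.50) and Sdhb (0.32). Genes with 0.5 to 1 kb of exons had medians of -0.036 for high over low and -0.10 for medium over low. Those with 2 to 4 kb had 0.30 and 0.15, and the few with under 0.5 kb had 0.17 and 0.21. Random lists were not matched on exon length, so what it adds to the oxidative phosphorylation median was not tested. Heat shock and dissociation genes had a median of -0.14 (-0.59 to -0.047), with 12 of 15 below 0, and of 0.0085 over all called cells. The chaperones Hspa1b and Hspa1a had -0.75 and -0.66 and Hspa8 had 0.29.

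Among genes with at least 50 CPM in a library compared, the 12 largest ratios of high over low were mostly in genes with long introns. Cfap77, a cilium gene with 125 kb of introns, had 4, 11357 and 23882 UMIs in the low, medium and high library (log2 high over low 11.83, 10.47 to 13.71). Il31ra, a cytokine receptor gene, had 0, 3514 and 4179 UMIs, at least 849-fold higher in CPM in high than in low. Airn (5.51), Camk1d (5.396), Cdk8 (5.19), Cmss1 (5.14), Mir142hg (4.78, with 1.43 kb of introns), Kcnq5 (3.22), Gphn (3.05), Dscam (2.82) and Setbp1 (2.67) were also among them. These genes were also higher in the medium than in the low library, and their high over medium ratios lay between -0.67 for Mir142hg and 0.48 for Cfap77. Genes among the 12 largest ratios the other way had at most 7.83 kb of introns, in Ndufb1-ps, and lay between -1.45 and -0.93. They included Atp5k, Ndufa3, Ndufb1-ps, Pet100 and Tomm7 of mitochondria, the histone genes Hist1h2ap, Hist1h2ae and Hist1h4d, and Bola2, Bloc1s1 and Dpm3. Ndufb1-ps and the histone genes have close paralogs, so their counts are uncertain. The ranking was not adjusted for exon length either.

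The ratio of high to low was higher for genes with longer introns. In CD8 T-like cells the median log2 ratio was 0.071 for 1260 genes with under 2 kb of introns and 1.26 for 165 genes with over 300 kb. For medium over low the same medians were -0.0088 and 1.19, and for high over medium 0.066 and 0.049. Spearman's rho of intron length with the ratio, across genes that are not independent replicates, was 0.423 for high over low, 0.496 for medium over low and -0.0493 for high over medium. In a cluster led by H2-Aa and Lyz2, genes of antigen-presenting myeloid cells, the high over low medians were -0.40 and 2.93, and in barcodes with 100 to 300 UMIs they were 0.11 and 1.33. After subtracting from each gene the median of genes of like intron length, high over low medians were 0.36 for proliferation, -0.48 for the interferon response, 0.11 for cytokine receptors, 0.050 for proximal signalling, -0.056 for inhibitory receptors and -0.00017 for glycolysis.

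**Figure D2:**
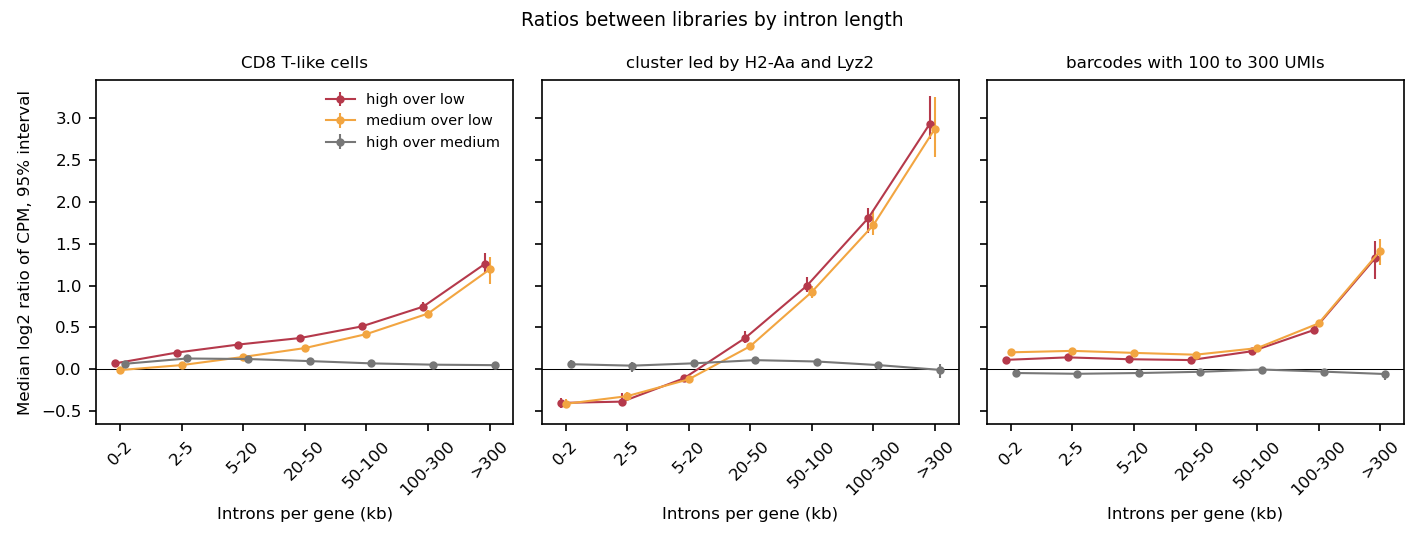
Median log2 ratio of CPM (vertical axis, no unit, with 95% intervals) for genes grouped by kilobases of introns (horizontal axis), in CD8 T-like cells, in the cluster led by H2-Aa and Lyz2 and in barcodes with 100 to 300 UMIs. Ratios to the low library climb to 1.26, 2.93 and 1.33 for high over low in the longest group, while high over medium ends at 0.049 in CD8 T-like cells.

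Key genes lie on mm10 as follows, all as whole gene models. Pdcd1 (ENSMUSG00000026285) is on chromosome 1 from 94038305 to 94052553, Tox (ENSMUSG00000041272) on chromosome 4 from 6686353 to 6991557 and Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361. Cblb (ENSMUSG00000022637) is on chromosome 16 from 52031225 to 52208048 and Rsad2 (ENSMUSG00000020641) on chromosome 12 from 26442746 to 26456452. Cfap77 (ENSMUSG00000079502) is on chromosome 2 from 28926949 to 29055066 and Il31ra (ENSMUSG00000050377) on chromosome 13 from 112519898 to 112594360.

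Effector genes went both ways between medium and low avidity TIL, with more of them lower in medium in CPM. The cytotoxic list had a median log2 ratio medium over low of -0.17 (-0.28 to 0.10), above 0.04% of random lists, with 14 of 22 intervals below 0 and 7 above. Gzmb had -0.17 (-0.19 to -0.14), Ifng -0.25 (-0.29 to -0.20) and Gzmc -0.45 (-0.58 to -0.32), against 0.76 for Tbx21 and 0.75 for Zeb2. Fos, an immediate-early gene, had the largest ratio downward among genes with at least 50 CPM (-0.78, -0.87 to -0.70), followed by Areg (-0.55), Fabp5 (-0.47), Sertad1 (-0.46) and Hist1h2ae (-0.45). The oxidative phosphorylation median was -0.21 (-0.23 to -0.081), with 12 of 16 below 0, as for Ndufb9 (-0.32) and Cox8a (-0.31). Proliferation stood at 0.082 (-0.053 to 0.17), with 8 of 20 intervals above 0 and 4 below, as for Mcm6 (0.34), Mki67 (0.15) and Ube2c (-0.40).

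The long-intron genes were higher in the medium than in the low library, and receptor and signalling lists moved with them. Cfap77 had a ratio of 11.35, Il31ra was at least 1080-fold higher, and Cdk8 (5.75), Airn (5.68) and Cmss1 (5.53) followed. Proximal signalling had a median of 0.26 (20 of 26 above 0), with Cblb at 1.001 and Cd3d at -0.16. Cytokine receptors had 0.32 (11 of 15 above 0), with Il12rb2 at 0.79 and Il18rap at 0.61. Inhibitory receptors had 0.28 (9 of 17 above 0), with Tox at 0.63, Entpd1 at 0.62, Pdcd1 at 0.31 and Havcr2 at 0.032 (-0.035 to 0.10). TCR-induced genes had 0.17 (12 of 19 above 0), with Irf4 at 0.76, Cd5 at 0.30, Nr4a1 at 0.22 and Cd69 at -0.24, residency genes 0.35 (8 of 13), glycolysis 0.20 (13 of 15, Slc2a1 at 0.60) and the interferon list -0.0078 (2 of 14), with Oasl1 at 0.88. The naive list had -0.012 (4 of 13), with Bach2 at 2.41 and Tcf7 at -0.012, and the heat shock list -0.041 (6 of 15), with Hsph1 at 0.52 and Atf3 at -0.43. Cd8a had 0.079. The median over all genes was 0.21.

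High and medium avidity TIL, whose ratios did not follow intron length, differed in proliferation and interferon genes and in single cytokine and granzyme genes. Proliferation had a median log2 ratio high over medium of 0.54 (0.40 to 0.60), above all 10000 random lists, with 19 of 20 intervals above 0: Ccna2 (cyclin A2) had 0.76, Ccnb2 0.75 and Mki67 0.51, and Tuba1b -0.13. The interferon list had -0.21 (-0.71 to -0.014), below all random lists, with 8 of 14 intervals below 0 and none above, as for Rsad2 (-1.13, -1.53 to -0.73) and Ifi44 (-1.05). Csf2, which encodes the cytokine GM-CSF, had the largest ratio upward among genes with at least 50 CPM (1.57, 1.40 to 1.75), but its 654 UMIs in the low library were also more than the 318 in the medium. The difference lay in the cluster with Xcl1, Csf2 and Il2, where Csf2 stood at 128 CPM in the medium and 869 in the high library, against 14.1 and 15.1 CPM in other CD8 T-like cells. Of that cluster's cells 86.6% had CD8 and CD3 UMIs and 65.1% a TCR contig. Penk (proenkephalin, 0.90), Crtam (0.89) and Gzmc (0.81) followed, with Ifng at 0.46 and Gzmb at 0.39. Hspa1b (-1.20) and Hspa1a (-1.13), Atp5k (-1.48), Hist1h2ap (-1.39) and Ndufb1-ps (-1.19) were lower in high. Genes with under 0.5 kb of exons had a high over medium median of -0.24 (102 genes), against 0.13 for those with 2 to 4 kb, and Atp5k and Hist1h2ap are among the short ones.

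Of the remaining lists, glycolysis had a high over medium median of 0.15 (13 of 15 above 0), with Eno1 at 0.39 and Hk2 at -0.38, and the heat shock list -0.091 (9 of 15 below 0). Inhibitory receptors had 0.12 (9 of 18 above 0), with Havcr2 at 0.33, Tigit at 0.26, Pdcd1 at 0.21 and Tox at -0.11. Cytotoxic genes also had 0.12 (13 of 22), and oxidative phosphorylation 0.10 (9 of 16), with Atp5b at 0.37 and Ndufa1 at -0.47. Cytokine receptors (0.080), proximal signalling (0.070), residency (0.059), TCR-induced (0.025) and naive genes (0.013) lay below the median gene, at 0.10. Within them Myb had 0.88, Ccr7 0.54, Il2ra 0.45, Tcf7 0.41, Cd247 0.36, Cd5 0.20, Nr4a1 0.18 and Cd8a 0.14, and Il7r had -0.45, Itga1 -0.41 and Myc -0.23.

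More cells had a Pdcd1, Lag3, Tox or Gzmb UMI in the high than in the low library after thinning to 2500 UMIs per cell. Thinning makes only the total UMIs per cell equal. Ribosomal protein genes took 29.9%, 26.7% and 23.1% of UMIs in the low, medium and high library, and the median gene had a log2 ratio high over low of 0.34. The ratio of Gzmb lay below that of the median gene, so its difference in share may reflect this offset. Pdcd1 was seen in 67.2% of low, 74.1% of medium and 78.2% of high avidity cells, a high minus low difference of 11.0 points (8.49 to 13.5). Lag3, an inhibitory receptor, was seen in 50.9%, 56.3% and 58.2% (7.28 points), Tox, with 298 kb of introns, in 33.0%, 43.8% and 42.3% (9.32 points) and Gzmb in 74.6%, 73.9% and 80.1% (5.49 points). Unthinned shares were 81.8%, 89.3% and 93.5% for Pdcd1, 71.5%, 80.7% and 87.0% for Lag3, 51.4%, 67.0% and 70.0% for Tox and 80.0%, 82.3% and 87.5% for Gzmb. Thinned to 1000 UMIs, the high minus low difference for Tox was 4.88 points (2.74 to 7.01). Genes with 100 to 300 kb of introns had a median log2 ratio high over low of 0.75, and relative to genes of like intron length the ratio of Tox was -0.50. In the cluster led by H2-Aa and Lyz2, 18.1% of barcodes had CD8 and CD3 UMIs and 12.5% a TCR contig, so it gives no clean background. It held 115, 95 and 77 cells before those too shallow for thinning were left out, so its shares rest on few cells. Thinned shares there were 16.8%, 5.33% and 8.47% for Pdcd1, 10.5%, 4% and 6.78% for Lag3, 10.5%, 2.67% and 3.39% for Tox and 18.9%, 9.33% and 13.6% for Gzmb, at median depths of 6739, 4893 and 4484 UMIs. Cd69, an early activation marker, was seen in 29.2%, 24.8% and 25.3% (myeloid cluster 13.7%, 2.67% and 10.2%), a difference of -3.87 points that was 0.850 points unthinned. Il7r was seen in 21.03%, 20.1% and 16.2%, below the 28.4%, 22.7% and 30.5% of the myeloid cluster, which therefore gives no background for it. Its high minus low value of -4.82 points was 0.556 points unthinned, so no difference is read from it. Mki67 was seen in 8.63%, 9.30% and 12.2% of CD8 T-like cells (unthinned 14.5%, 17.3% and 24.7%), a high minus low difference of 3.58 points (1.84 to 5.31). The myeloid cluster had 4.21%, 12% and 16.9%, on few cells. Whether the difference is particular to CD8 T-like cells was therefore not decided, and none is read from Mki67 shares. Ifng was seen in 51.8%, 48.8% and 52.3% (unthinned 66.2%, 67.4% and 74.9%, myeloid cluster 17.9%, 8% and 5.08%) and Gzmk in 10.5%, 9.91% and 10.4% (unthinned 17.6%, 20.5% and 25.1%, myeloid cluster 2.11%, 1.33% and 1.69%).

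Antibody tags for PD-1, LY108 (the protein of Slamf6, a marker of stem-like exhausted T cells) and TIM3 were highest on high avidity cells, in counts per cell. PD-1 averaged 291, 288 and 355 counts per cell in the low, medium and high library, a high over low ratio of 1.22 (1.22 to 1.22). LY108 averaged 39.4, 34.8 and 46.5 (ratio 1.18) and TIM3 86.6, 70.9 and 96.7 (1.12). High over medium ratios were 1.23, 1.34 and 1.36, and medium over low ratios 0.991, 0.882 and 0.819. Minus the mean of barcodes with 100 to 300 UMIs, medium over low ratios were 1.03 for PD-1, 1.02 for LY108 and 0.919 for TIM3. Divided by that mean, PD-1 was 9.22, 14.3 and 16.1 in the low, medium and high library. LY108 was then 2.57, 3.42 and 3.78 and TIM3 3.10, 4.17 and 5.12. Tag counts over all barcodes were 12439580, 7945496 and 9254906. The ratios of raw counts per cell were not scaled for this depth and may partly reflect it. No direction is therefore read for these tags between low and medium. CX3CR1 averaged 77.1, 44.7 and 48.7 counts (high over low 0.632, medium over low 0.580, high over medium 1.09), close to the 63.0, 38.2 and 40.9 in barcodes with 100 to 300 UMIs, so it was read as background. Under the first cell rule, which keeps the largest cells, the high over low ratios were 0.920 for PD-1, 0.750 for LY108 and 0.824 for TIM3, and over all called cells those of LY108 and TIM3 were 0.795 and 0.988. Under centred log ratios the high minus medium difference of PD-1 was -0.00662. Within each library the tags of PD-1, LY108 and TIM3 were higher on cells with a UMI of their gene, while CX3CR1 medians with and without were 68 and 64, 41 and 42, and 45 and 44. TIM3 medians in cells with and without a Havcr2 UMI were 85 and 44 in the low, 74 and 32 in the medium and 90 and 39 in the high library.

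**Figure D3:**
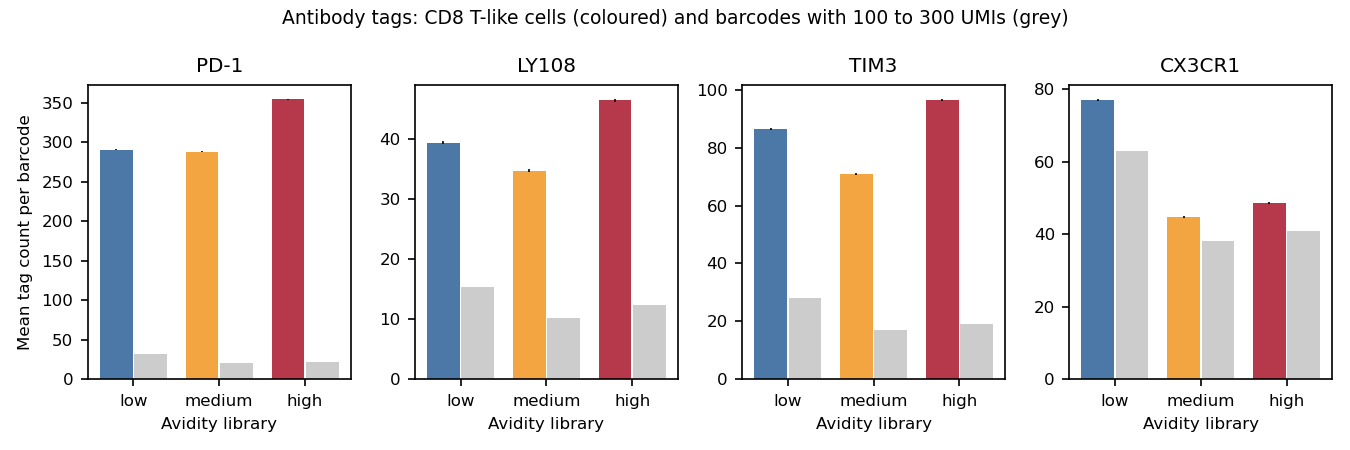
Mean tag counts per barcode (vertical axis) of 4 antibodies in CD8 T-like cells of each avidity library (coloured bars, horizontal axis, with 95% Poisson intervals) and in barcodes with 100 to 300 UMIs (grey bars). PD-1 stands far above background (355 against 22.02 in the high library) and CX3CR1 does not (48.7 against 40.9).

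The high avidity library was dominated by few clonotypes. Paired chains were found in 1376 low, 1275 medium and 1897 high avidity cells, 52.9%, 55.8% and 72.1% of CD8 T-like cells. The largest clonotype held 12.3% of paired cells in the low library (10.6 to 14.1), 13.9% in the medium (12.03 to 15.9) and 45.4% in the high (43.1 to 47.7), and the 10 largest held 59.2%, 58.4% and 84.3%. Thinned to 1275 cells, the libraries held means of 169.9, 166 and 91.0 clonotypes, and the inverse Simpson index, an effective number of clonotypes, was 19.5, 19.7 and 4.24.

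The clonotype that led the high library, TRAV6-3 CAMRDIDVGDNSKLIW with TRBV14 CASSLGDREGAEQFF, held 12.1% (10.5 to 13.98) of the low and 13.9% of the medium library. It was also the largest clonotype shared by all 3. TRAV6-1 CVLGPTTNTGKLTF with TRBV2 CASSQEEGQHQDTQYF held 3.34%, 4.16% and 14.2%. The clonotype that led the low library, TRAV13-4/DV7 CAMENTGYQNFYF with TRBV1 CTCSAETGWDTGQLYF, held 12.3%, 10.2% and 3.43%. Among clonotypes chosen after their values were seen, TRAV1 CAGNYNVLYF with TRBV13-1 held 1.53%, 0.863% and 6.06%, and TRAV6-7/DV9 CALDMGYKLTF with TRBV5 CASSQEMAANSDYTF held 9.01%, 8.94% and 2.85%. V gene use followed these clones. TRBV14 was used by 12.1%, 13.9% and 45.4% of cells but by 0.565%, 0.602% and 0.909% of clonotypes, TRBV1 by 20.6%, 20% and 8.12% of cells, and TRBV2 by 7.78%, 7.92% and 14.97%. TRAV6-3 was used by 12.6%, 14.8% and 45.4%, TRAV13-4/DV7 by 18.7%, 18.5% and 6.54%, and TRAV6-1 by 3.42%, 4.31% and 14.5%. Under the first cell rule TRBV14 held 2.47%, 7.25% and 51.9%.

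**Figure D4:**
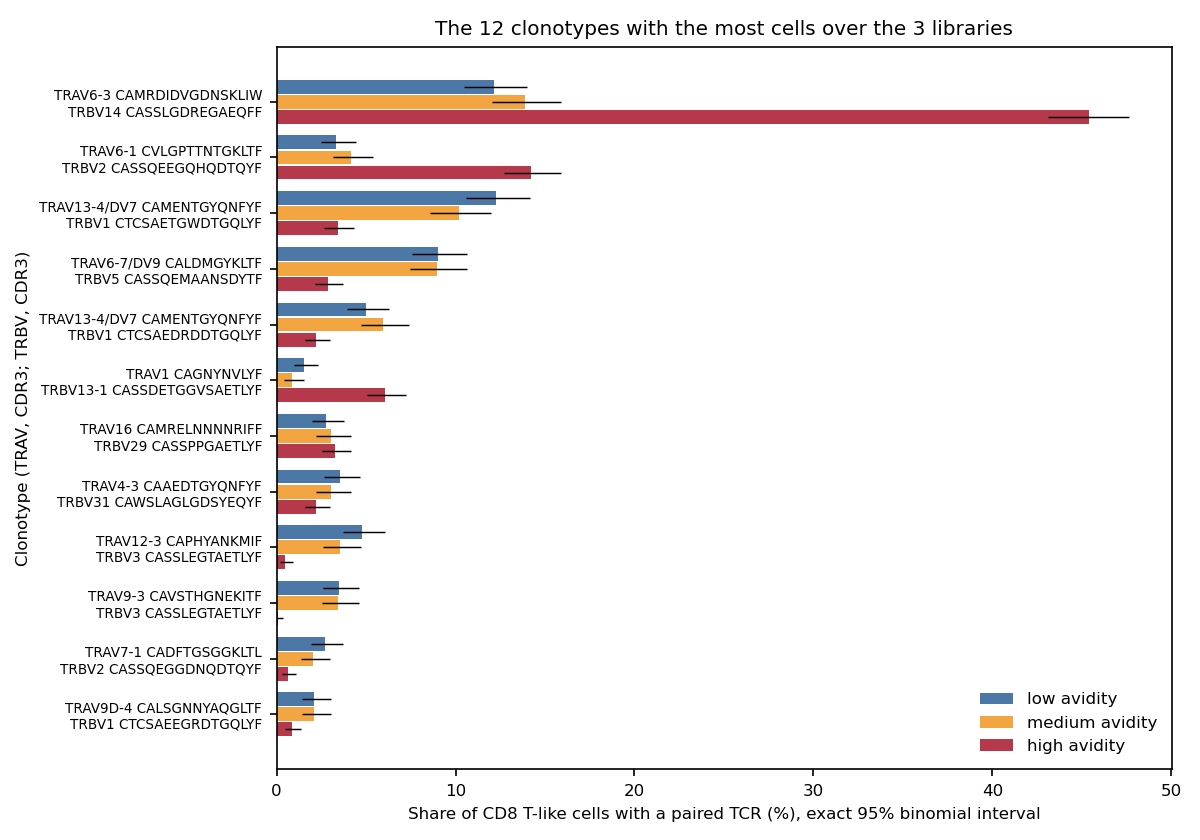
Share of paired CD8 T-like cells (horizontal axis, %, with exact 95% binomial intervals) held by the 12 clonotypes with most cells (vertical axis) in the low, medium and high avidity libraries. The TRAV6-3 and TRBV14 clonotype goes from 12.1% in low to 45.4% in high, and the clonotype of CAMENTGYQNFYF with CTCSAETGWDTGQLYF from 12.3% to 3.43%.

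Most cells belonged to clonotypes found in more than 1 avidity class. The low and medium libraries shared 96 clonotypes, which held 93.3% of low and 92.9% of medium cells, with a Morisita-Horn overlap of 0.981. Low and high shared 58, which held 82.9% of low and 94.4% of high cells (overlap 0.5003), and medium and high shared 66, which held 81.5% and 96.2% (0.556). All 3 shared 51 clonotypes. Barcodes found in both libraries of a pair numbered 3, 3 and 4, against 2.45, 3.64 and 3.38 expected by chance, and 1 of those of low and high carried the same clonotype in both.

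Cells of expanded clonotypes were compared with cells of single-cell clonotypes inside each library, with 1164, 1065 and 1765 expanded cells and 89, 78 and 50 single ones. The 3 libraries are not independent here, since the 51 clonotypes found in all of them held 82.0% of low and 94.0% of high avidity cells. In the high library, 861 cells belonged to the TRAV6-3 and TRBV14 clonotype and 270 to the TRAV6-1 and TRBV2 clonotype. Naive, memory and stem-like genes were lower in expanded clonotypes in 3 of 3 libraries, with log2 ratios from -1.23 to -0.93. Inhibitory receptor genes were higher in 3 of 3, from 0.19 to 0.39, as were proximal signalling (0.10 to 0.21) and heat shock genes (0.056 to 0.16). Interferon genes (-0.33 to -0.22) and glycolysis genes (-0.23 to -0.11) were lower in 3 of 3. In the medium and high libraries, but with intervals that span 0 in the low, residency (0.048 to 0.54), TCR-induced (0.028 to 0.36) and cytotoxic genes (-0.029 to 0.45) were higher and oxidative phosphorylation genes (-0.13 to 0.025) lower. Cytokine receptor genes had 0.11 (0.046 to 0.18) in the medium library and intervals that span 0 in the others. Proliferation genes were higher in expanded cells of the low library (0.43) and lower in those of the medium (-0.82) and high (-0.22) library. Under the first cell rule the median over the libraries was 0.69 for the interferon list, against -0.23, and 0.071 for proliferation, against -0.22. In the low library, with 4 single cells left, that rule gave -1.86 (-1.92 to -1.80) for cytotoxic, -0.42 (-0.60 to -0.24) for inhibitory receptor, -0.20 for proximal signalling, -0.18 for TCR-induced and -0.42 for residency genes.

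The same clonotypes in low and high allow the libraries to be compared with the TCR held fixed, though any offset between libraries remains. Over 19 clonotypes with at least 5 cells on each side, cytokine receptor genes were higher in high in 19 (median log2 ratio 0.39, 0.33 to 0.43), glycolysis genes in 18 (0.36), inhibitory receptors in 17 (0.30, 0.22 to 0.41), proximal signalling in 17 (0.25) and naive, memory and stem-like genes in 16 (0.76, 0.091 to 1.18). The intervals of all 5 medians span 0.34, the high over low median over all genes of the whole libraries. That value weights each gene equally, while the clonotype values come from UMIs summed over each list. Whether any of them exceeds the offset was therefore not decided. Oxidative phosphorylation genes were lower in 18 (-0.12) and interferon genes in 15 (-0.23, -0.72 to -0.045). Proliferation had 0.42 with an interval that spans 0 (12 of 19 higher), cytotoxic genes 0.17 (13), TCR-induced 0.12 (12), residency 0.11 (10) and heat shock 0.014 (10). Over 17 clonotypes of medium and high, proliferation was higher in high in 16 (0.56, 0.18 to 1.25) and interferon genes lower in 12 (-0.22), while the medians of inhibitory receptors (0.038), proximal signalling (0.053) and cytokine receptors (0.059) had intervals that span 0. With the first cell rule 4 clonotypes were left, and the naive, interferon and proliferation medians were -0.71, 0.030 and -0.34. With list genes of under 5 kb of introns the TCR-induced median was -0.28, that of cytokine receptors 0.11 and that of proximal signalling 0.082.

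A pair of clonotypes, chosen with their genes after the data were seen, differed from other paired cells in each library. Cells of the TRAV6-1 and TRBV2 clonotype had 8924, 7222 and 9223 CPM of the granzyme genes Gzmd, Gzme and Gzmf together in the low, medium and high library, against 2822, 2044 and 2336 in other paired cells. Cells of the TRAV6-3 and TRBV14 clonotype had log2 ratios of 2.22 (1.48 to 2.94), 2.46 (1.63 to 3.26) and 3.40 (2.65 to 4.24) for Prss2, a trypsinogen gene, on 26, 24 and 153 UMIs. Prss2 was chosen for a high ratio in all 3 libraries, so its agreement between them follows from the choice.

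**Figure D5:**
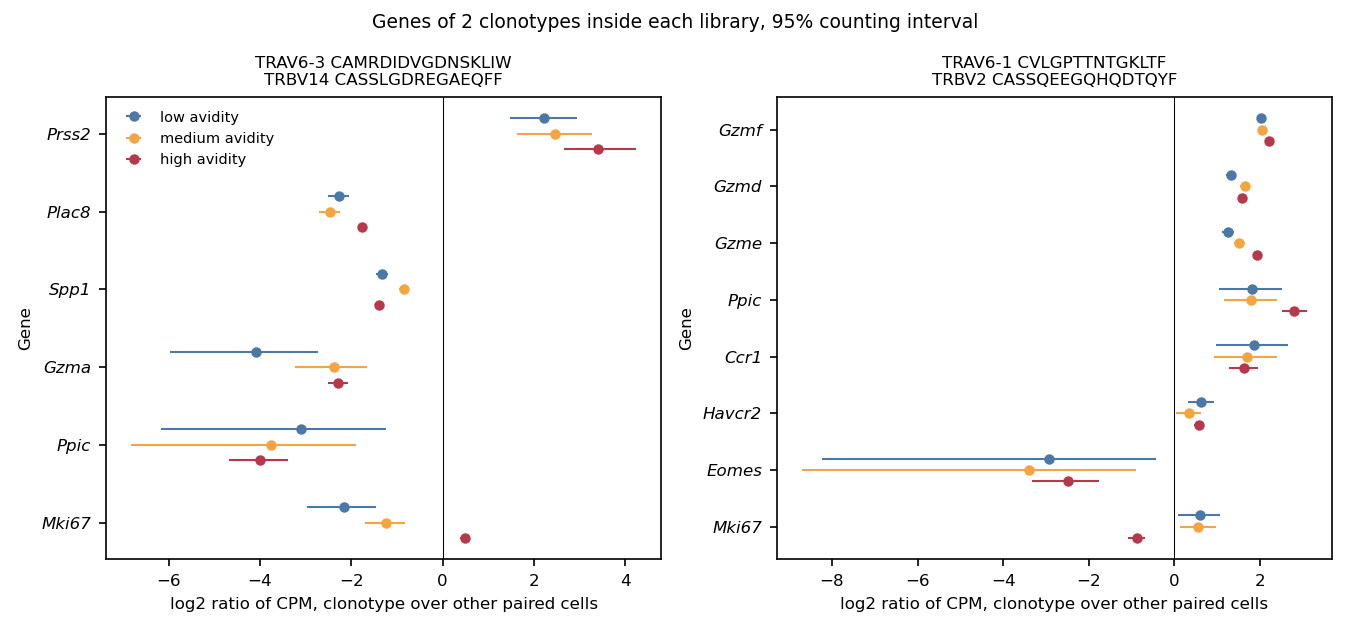
Log2 ratio of CPM (horizontal axis, no unit, with 95% counting intervals) of selected genes (vertical axis) in cells of 2 clonotypes over all other paired cells of the same library, for the low, medium and high avidity libraries. Gzmf stood at 2.02, 2.05 and 2.21 in the TRAV6-1 and TRBV2 clonotype, and Prss2 at 2.22, 2.46 and 3.40 in the TRAV6-3 and TRBV14 clonotype.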

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

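Tests chosen only after the result was seen were the one of the myeloid cluster for avidity as the whole cause, and the one of barcodes carried over between libraries. The third pattern was picked from the leading genes of a cluster that lay mainly in the medium and high libraries, among them these granzymes, Trav6-1 and Trbv2, before its values per clonotype and library were seen.

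Gene levels of the low library stood apart from both other libraries, by more the longer a gene's introns. If avidity were the whole cause, myeloid cells caught in the sort would not share the trend, but in the cluster led by H2-Aa and Lyz2 the median log2 ratio high over low of genes with over 300 kb of introns exceeded that of genes with under 2 kb by 3.33, which argues against it. In barcodes with 100 to 300 UMIs, which hold mainly free RNA, the same difference was 1.22, above the 1 set beforehand, so a candidate explanation is that intronic reads were counted in the medium and high matrices and not in the low one. More unspliced or nuclear RNA with the same counting in all 3 stays open: single-exon models inside an intron of a same-strand gene had a ratio 0.12 (-0.010 to 0.31) above other single-exon models, between the values set for yes and no. A planned test that took out free RNA decided nothing, since the subtraction added noise and raised the spread of ratios from 0.452 to 0.624, and it was replaced after its value was seen.

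The TRAV6-3 and TRBV14 clonotype held 3.74 times as large a share of paired cells in the high as in the low library. Uneven recovery of TCR contigs as the whole cause is argued against by cells without a TRB contig, in which the share of Trbv14 among Trbv UMIs was 2.17 times as high (1.90 to 2.48) in high as in low. Over all CD8 T-like cells that share was 9.77% in low and 47.0% in high. It was 13.8% and 58.0% in cells with a TRB contig, against 3.82% and 8.30% without, so recovery may still shift shares of paired cells. Of the low library's barcodes of this clonotype, 0.599% (0.0152 to 3.29) also carried it in the high library. This is below a 10% limit that was set after the data were seen, so it shows little barcode overlap and no more. The clonotype had 167 cells in low and 861 in high, so carry-over from low could not give the high share, whatever the test showed. That cells with this TCR bind the antigen more strongly, and so are sorted as high avidity more often, stays open and untested, since binding was not measured here, and they are also a large part of the low and medium classes. A difference in the mice that gave the cells of each class stays open as well, although 51 clonotypes were found in all 3.

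Cells of the TRAV6-1 and TRBV2 clonotype carried more Gzmd, Gzme and Gzmf RNA, granzymes close together on chromosome 14, than other paired cells in every library. A state of the medium and high libraries only is argued against by the low library, which gave 10 cells to the cluster that drew attention to it, against 324 of the medium and 481 of the high library, and where the clonotype had 3.16 times (3.04 to 3.29) the CPM of these genes. A difference in UMIs per cell is argued against by thinned cells, in which the share with a UMI of these genes was at least 1.72 times as high, and more dividing cells by the ratio outside the proliferating cluster, at least 3.32. The 3 genes are near copies of each other, so their counts are uncertain one by one and were summed. The TCR, the history of the clone and a different mouse of origin stay open, and none of them was tested.

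Barcodes of an intron-rich cluster outside the CD8 T-like cells numbered 481 in the medium and 540 in the high library, against 0 in the low. They were outside the CD8 T-like cells compared and entered alternatives such as those with all called cells or with this cluster. Productive TRB contigs on barcodes not marked as cells, which were not used, numbered 1827 in the low, 3890 in the medium and 5520 in the high library. Proliferation genes in expanded over single clonotypes had a log2 ratio of 0.43 in the low library and of -0.82 and -0.22 in the medium and high ones, a difference in direction between classes that was not tested.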

How the results depend on the processing

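The alternatives on intron length, on free RNA, on the intron-rich cluster and on medium in place of low, and the use of the 1000 UMI minimum as the main setting, were chosen after seeing the data. No paired analysis was possible because each class has 1 library, so no fit with a term for pairs could be made. Cells were matched by clonotype instead, in the comparison of the same clonotypes. Of 526 values under alternatives, 371 stayed within the main interval, 130 moved beyond it and 25 with a called direction reversed. Counts were held to within 1.5 times the main count instead, and centred log ratios to their direction. Values that changed sign inside a main interval that spans 0 are among the 371. In list medians high over low these were naive genes at -0.061 and cytotoxic genes at -0.0058 relative to genes of like intron length, naive genes at -0.34 with under 5 kb of introns, TCR-induced genes at -0.042 with median-of-ratios size factors and interferon genes at 0.0080 with the first cell rule. With that rule, proliferation in expanded clonotypes was at 0.071. The cause was not tested unless the setting's construction gives it. All values under a clone size limit of 3 or 10 cells, resolution 2, no low-count filter, paired cells only, no proliferating cluster and the mean in place of the median stayed within it. A 5% mitochondrial limit was applied to the number of cells called alone and left 3154, 2874 and 3307. Depth limits genes such as Tcf7 and Itgae, on 119 and 21 UMIs in the low library, and the 50 to 89 single-cell clonotypes.

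With the first cell rule 489, 424 and 853 cells were called. The list medians high over low were 0.17 for glycolysis, 0.52 for inhibitory receptors and -0.060 for proliferation, which reversed. Tag ratios high over low reversed for PD-1 (0.920), LY108 (0.750) and TIM3 (0.824) and moved for CX3CR1 (0.555), and high over medium were 1.17, 1.29, 1.17 and 1.03 and medium over low 0.787, 0.582, 0.707 and 0.537 in that order. The 10 largest clonotypes held 87.8% of the high and 64.5% of the medium library, the largest 51.9% of the high and 9.88% of the low, and TRBV14 2.47%, 7.25% and 51.9%. Clonotypes shared fell, since fewer cells were left, to 13 in all 3 libraries, 17 in low and high, 21 in low and medium and 15 in medium and high, and held 88.6% of high, 79.0% of medium and 85.5% of high cells. Expanded over single clonotypes gave -0.084 for cytokine receptors, 0.54 for cytotoxic, -1.25 for naive, 0.23 for proximal signalling, 0.63 for residency and 0.69 for interferon genes, which reversed. The same clonotypes gave 0.48 for cytotoxic, 0.63 for inhibitory, -0.34 for proliferation and 0.42 for residency genes, and naive (-0.71) and interferon genes (0.030) reversed.

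With all called cells in place of CD8 T-like cells, list medians were 0.95 for TCR-induced, 1.16 for cytokine receptor, 0.91 for cytotoxic, 0.085 for glycolysis, 1.11 for inhibitory, 1.13 for naive, -0.65 for oxidative phosphorylation, 1.05 for proximal and 1.03 for residency genes, and heat shock (0.0085) and proliferation (-0.032) reversed. Other cells and the intron-rich barcodes then enter the sums. Tag ratios high over low were 0.607 for CX3CR1 and 1.14 for PD-1, LY108 (0.795) and TIM3 (0.988) reversed, and high over medium were 1.11 for CX3CR1, 1.17 for LY108 and 1.28 for TIM3. Medium over low were 0.931 for PD-1, 0.679 for LY108, 0.774 for TIM3 and 0.548 for CX3CR1. Minus empty barcodes, high over low ratios were 0.556 for CX3CR1, 1.42 for LY108, 1.28 for PD-1 and 1.33 for TIM3, and high over medium 1.197, 1.39, 1.24 and 1.44. Medium over low then reversed for PD-1 (1.03) and LY108 (1.02) and was 0.919 for TIM3 and 0.464 for CX3CR1. With centred log ratios, high minus medium reversed for CX3CR1 (-0.127) and PD-1 (-0.00662), and medium minus low for PD-1 (0.190) and LY108 (0.0824).

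Median-of-ratios size factors, which take the median gene as unchanged, gave 0.12 for cytokine receptor, -0.12 for cytotoxic, -0.43 for oxidative phosphorylation, 0.29 for proliferation and 0.027 for proximal genes, and reversed glycolysis (-0.016), inhibitory (-0.018) and residency genes (-0.067). Minus the median of genes of like intron length, cytokine receptors were at 0.11, proliferation at 0.36 and proximal genes at 0.050, and glycolysis (-0.00017) and inhibitory genes (-0.056) reversed. With genes of under 5 kb of introns, TCR-induced genes were at -0.073, glycolysis at 0.19 and proximal genes at 0.15. High over medium in place of high over low gave 0.080 for cytokine receptor, 0.15 for glycolysis, 0.12 for inhibitory, 0.10 for oxidative phosphorylation and 0.070 for proximal genes. CPM without mitochondrial and ribosomal genes gave 0.18 for glycolysis, taking out free RNA 0.94 for proliferation, each clonotype weighted equally 0.38 for cytotoxic and 0.59 for proximal genes, and leaving out the largest clonotypes 0.38 for cytotoxic genes.

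In the same clonotypes, list genes with under 5 kb of introns gave -0.28 for TCR-induced, 0.11 for cytokine receptor and 0.082 for proximal genes, and medium and high in place of low and high gave 0.059 for cytokine receptor, 0.038 for inhibitory and 0.053 for proximal genes and reversed oxidative phosphorylation (0.059).

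The share of CD8 T-like cells was 82.5% in low at resolution 0.5, 85.9%, 83.3% and 86.4% by CD8 and CD3 UMIs, 81.8% in low and 75.3% in high without doublet removal, and 88.0% in medium and 88.6% in high with the intron-rich cluster. The contigs marked 2229, 2037 and 2612 barcodes as cells, of which 2155, 1933 and 2377 passed the gene, mitochondrial and doublet filters. With TRB-only clonotypes the 10 largest held 82.4% of high, and those shared by low and high held 96.0% of high. Unthinned, the differences for Cd69 (0.850 points) and Il7r (0.556 points) reversed. Thinned to 1000 UMIs, those for Tox (4.88 points), Entpd1 (5.66), Slamf6 (0.146) and Il7r (-1.40) moved. The planned split by hashtag was not run, as the feature list holds 0 hashtags.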

Other observations

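The clonotype comparisons below were chosen after their values were seen, from all clonotypes with at least 20 cells in each library, and their genes likewise. No hypothesis was tested here.

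Cells with stem-like genes carried more LY108 and less TIM3 protein in each avidity class. Cells of the cluster led by Dapl1, Ccr7 and Tcf7 had median LY108 tag counts of 89, 60 and 67.5 in the low, medium and high library, against 24, 22 and 27 on other CD8 T-like cells, and TIM3 counts of 30, 22 and 26.5 against 63, 53 and 74. Gzmb RNA stood at 356, 381 and 581 CPM there, against 1864, 1702 and 2268 elsewhere, though RNA levels of genes that help to define a cluster follow from the clustering. The cluster with Xcl1, Csf2 and Il2 carried less PD-1 protein, with medians of 102, 123.5 and 127 against 258, 278.5 and 340. Its Ifng RNA stood at 3810, 1570 and 4109 CPM against 570, 494 and 569, and its Csf2 RNA at 1299, 128 and 869 CPM. In the cluster led by Spp1 and Penk, TIM3 medians were 122 in the medium and 139.5 in the high library, against 49 and 67 on other cells, while PD-1 medians were 188 and 218.5, against 275 and 341.5.

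Genes of single clonotypes came from a ranking by the smallest ratio in the same direction over all 3 libraries. That the RNA ratios below agree between libraries therefore follows from the choice. Cells of the TRAV6-3 and TRBV14 clonotype had log2 ratios over other paired cells of the same library of -2.27, -2.48 and -1.76 for Plac8. Its share of cells in the proliferating cluster was 1.80% in the low, 1.13% in the medium and 12.2% in the high library, against 6.45%, 6.10% and 8.69% of other paired cells. Cells of the TRAV6-1 and TRBV2 clonotype had ratios of 1.87, 1.70 and 1.62 for the chemokine receptor gene Ccr1 and of 0.82, 1.14 and 1.32 for Cd5. Cells of the TRAV4-3 and TRBV31 clonotype had ratios of 1.40, 1.199 and 1.36 for Gzmk and of 0.83, 0.86 and 0.94 for Gzmb, with TIM3 medians of 98, 64 and 122 against 59, 50 and 72. Cells of the TRAV16 and TRBV29 clonotype had ratios of 2.04, 2.52 and 1.40 for Klra3, an NK cell receptor gene.

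Some chains recurred. The TRAV13-4/DV7 CDR3 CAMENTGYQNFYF, from 2 TRA nucleotide sequences, was found in 10 clonotypes, all with TRBV1, in 580 cells. The TRB chain TRBV3 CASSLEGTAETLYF, with 1 nucleotide sequence, was found in 214 cells as a pair with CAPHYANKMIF (120) or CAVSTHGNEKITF (94), and 143 of these cells carried both TRA chains. It is therefore probably 1 clone, which the rule of most TRA UMIs counted as 2 clonotypes in the values above. More than 1 TRA was found in 125, 126 and 36 paired cells of the low, medium and high library. The 143 cells with both of these TRA chains are among them, so these numbers also follow the size of that clone. Its 2 clonotypes held 66 and 48 cells in the low, 45 and 44 in the medium and 9 and 2 in the high library. Among genes with under 5 kb of introns, Maz (0.89), Penk (0.80), Rrm2 (0.67), Nfkb2 (0.64), H2-Q6 (0.61), Tubb5 (0.59) and Cdk4 (0.56) had high log2 ratios of high over low.

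A cluster with leading genes Wfdc2, Hspb1, Ckb, Nppb, Krt8 and Rhox5 held 222, 42 and 47 cells at a median of 69607 UMIs. It was not named, and its cells enter the values over all called cells.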
